A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

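Total RNA of W303 yeast, labelled as lacking the 3 G1 cyclin genes and carrying a CLN2 gene under the MET3 promoter, was measured on 12 Agilent 2-colour arrays, 1 for each time point from 5 to 60 min. Per the labels' protocols, cells grew overnight in complete synthetic medium with glucose, were moved to medium lacking methionine to arrest, and were released by adding methionine. RNA was isolated with a RiboPure kit and labelled with Agilent's Quick Amp 2-colour kit, per the labels' protocols. The labels place the time point RNA in Cy3 and the 0 min RNA in Cy5 on every array, with no dye swap. Each time point is a group of 1 array.

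Per the file headers, the arrays were read with Agilent Feature Extraction 9.5.3.1, which the submitters' processing notes also name. The mean and background intensity of each spot were deposited as read by the scanner software, without normalization. Per the file headers, the processed intensities were background-subtracted with a spatial detrend and dye-normalized by a linear and LOWESS method, and their LogRatio is log10 of Cy5 over Cy3. The authors' deposited table holds a log10 ratio per spot and array that differed from LogRatio by at most 0.005, so its scale and direction are settled, and it has no further centring. The medians of its columns were 0 at 5, 10, 15, 20, 25, 50 and 60 min, 0.00199 at 30 min, 0.00891 at 35 min, 0.00825 at 40 min, 0.00145 at 45 min and 0.00257 at 55 min. The genome build named in the file headers differs from that of the gene table used here, so no coordinates are given, and the R64 gene table was used for names only. Of the gene identifiers 5756 matched that table, and 500 kept the name in the files.

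Each array held 13048 spots, of which 536 were control spots. Mean signals were corrected with normexp (offset 50) and normalized by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with data.table (version 1.17.8). Between 1 and 13 outlier spots per array were left out. Saturated spots were kept. The 2 spots of each gene's 1 probe were averaged. Genes well above background in either channel on at least 3 arrays were kept, which left 6149 of 6256. The main value is log2 of Cy3 over Cy5.

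A natural cubic spline of time with 4 degrees of freedom and an intercept was fitted to the 12 arrays with lmFit and eBayes, leaving 7 residual degrees of freedom. Genes were called by the moderated F test of the whole curve and by contrasts of the fitted curve at 20 minus 5 min, 40 minus 20 min and 60 minus 40 min, with Benjamini-Hochberg adjustment at 0.05. The reference channel control applied the same F test to log2 Cy5 after normexp and quantile normalization. CLB6, dim in Cy3 at 5 min, has a bound from normalized log2 signals after loess and Aquantile. The bound sets Cy3 at a later time against Cy3 at 5 min and does not compare the dyes, but Cy5 enters it through the normalization.

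Before the data were examined, the tests, the alternatives other than those named as added, the rule for named genes and 18 gene lists were fixed. The first sensitivity and artifact scripts departed from this plan, with a copied Aquantile row, an added condition on p and missing rows, and were corrected after results had been seen. Of the 18 lists 1 and the genes named only through it are not reported here, although it stayed in the adjustment; the other 17 were the engineered G1 cyclins, SBF targets, MBF targets, histones, Hcm1 targets, the CLB2 cluster, the MCM cluster, methionine and sulfur assimilation, Gcn4 targets, ribosomal proteins, ribosome biogenesis, general stress response, glucose-repressed genes, the phosphate regulon, pheromone response and a-specific genes, alpha-specific genes and meiosis genes. No gene was in more than 1 of them. Lists of purine biosynthesis and hexose transporters were added after the values were seen. Lists were tested with limma's camera (preset correlation 0.01, and an estimated correlation beside it) and fry, adjusted over the 18 lists and 3 contrasts, and for the 2 added lists over all 20 lists and 3 contrasts (60 tests). The rule names CLN1, CLN2, CLN3 and MET3, for each contrast the 5 called genes with a symbol that rose most and the 5 that fell most, and for each list up to 4 called members with the largest fitted range.

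Half-rise times were taken from the fitted curves of called genes that rose by at least 0.5 and compared between 5 pairs of lists by two-sided permutation tests of the difference of medians, with 100000 resamples. The splits of these lists, the 9 histones included, were too many to enumerate. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for these tests and the plots.

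The fits were tested on simulated data of 6149 genes. For the curve from 5 to 60 min, 14 of 50 genes with a bump of 0.5 on the log2 scale were recovered, 42 of 50 with 1, 49 of 50 with 2 and 50 of 50 with 3, with 7 false calls. The median difference of the fitted from the true half-rise time was -2.03, -1.87, -1.87 and -1.7 min at these sizes, so fitted times were early. All simulated peaks lay at 50 min or earlier, so curves still rising at the last array were not simulated. Of simulated genes that changed by at least 1, 33 of 37 were recovered from 5 to 20 min, 75 of 78 from 20 to 40 min and 59 of 61 from 40 to 60 min, with 1, 6 and 3 false calls. The median fitted change was 1.08, 0.895 and 0.994 of the true one. For lists from 5 to 20 min, 1 list of 20 genes shifted by 0.5 was recovered and 0 of the other lists were called. The simulated noise was independent between genes, so false calls from errors shared by genes on an array could not appear. In the real data the estimated correlation within a list reached 0.52, for the histone genes, and the simulation does not test camera on such lists.

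The alternatives fixed in advance were Feature Extraction's processed signals, the authors' deposited table, no background subtraction, median centring, Aquantile normalization, 2 other filters, splines with 3 and 5 degrees of freedom, the slide as a term, the second slide alone, a curve through 0 at 0 min, eBayes with trend and robust, linear interpolation for half-rise times, an estimated correlation for lists, and each time point left out. Scale normalization, Cy3 alone, the first slide alone and some settings for lists were added after seeing the data.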

Results

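RNA of budding yeast was followed at 12 time points, from 5 to 60 min in steps of 5 min, after cells labelled as lacking the G1 cyclin genes were released from an arrest. What caused the arrest was not tested. The strain was W303 and grew in synthetic medium with glucose. Per the labels, the 3 G1 cyclin genes CLN1, CLN2 and CLN3 were deleted, and the only source of a G1 cyclin was a CLN2 copy driven by the promoter of MET3, the ATP sulfurylase of sulfate assimilation. The labels place the arrest in medium without methionine and the release at the addition of methionine. The rise of the methionine genes described below argues against that order. Each time point was hybridized once, on a 2-colour Agilent array, with the time point RNA in Cy3 and RNA of the 0 min culture in Cy5. There were no replicates at any time point, so every p-value below measures scatter about a smooth curve through 1 time course and not the spread between cultures. The series asks how RNA levels follow the release. The same 0 min RNA stands for the control on all 12 arrays, and its own spread between cultures was not measured.

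The arrays held 6256 genes, of which 6149 were tested. The median Cy3 signal lay between 1688 and 3263 and the median Cy5 signal between 3726 and 4348, against a background median of 33 to 36.5 in Cy3 and 49.5 to 50 in Cy5. The Cy3 median was lower late in the course, at 2756 to 3263 from 5 to 30 min and 1688 to 2008 from 45 to 60 min. Sample brightness thus followed time, and loess within each array removes a change shared by all genes. Between 95% and 97.6% of spots were well above background in Cy3, and between 94.3% and 97.7% in Cy5. The 2 spots of a probe differed with an SD of 0.0319 in log2 ratio, and the median residual SD of a gene about its fitted curve was 0.141. The number of arrays limits the precision. The arrays lay on 2 slides, with 5 to 20 min on the first and 25 to 60 min on the second. Log2 ratios are given as time point over 0 min, which is opposite in sign to the authors' deposited table, whose values are log10 of 0 min over time point.

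The genes named in the strain's genotype were examined first. CLN2 rose from a log2 ratio of -0.13 at 5 min to 2.47 at 35 min and was back at 0.50 at 60 min. Its fitted change from 5 to 20 min was 1.88 ± 0.17 (SE; limma adjusted p = 2.33e-05). MET3 followed a similar course, from 0.71 at 5 min to 5.91 at 35 min and 2.93 at 60 min, and rose by 4.16 ± 0.15 from 5 to 20 min (limma adjusted p = 5.15e-09). The Cy5 signal of CLN2, which should be constant, rose and fell with Cy3 over a fitted range of 2.17. In Cy3 alone, a setting added after seeing the data, the change of CLN2 from 5 to 20 min was 3.43. CLN3 lay between -0.66 and -0.13 on all arrays. It passed the F test of the whole curve with a fitted range of 0.46 (limma adjusted p = 0.0252). This call was lost with the slide as a term (range 0.31, adjusted p = 0.239), with median centring (0.13, 0.842) or scale normalization (0.24, 0.327). It was also lost without the 40, 45, 50, 55 or 60 min array (highest adjusted p = 0.108). Within the second slide, which holds only the later times, CLN3 did not pass either (0.34, 0.125). The CLN3 range was 1.06 with Feature Extraction's processed signals and with the authors' deposited table. None of its 3 changes between the chosen times passed the threshold in the main fit. The CLN3 change from 20 to 40 min, -0.19, passed at -0.46 with Feature Extraction's processed signals (limma adjusted p = 0.0265), at -0.46 with the authors' deposited table (0.0266) and at -0.27 without the 35 min array (0.047), was -0.0084 with the slide as a term, -0.10 with a spline of 5 degrees of freedom and -0.098 without the 5 min array, and turned to 0.11 with median centring. Of these 3 genes as a list, 1 rose from 5 to 20 min, 2 rose from 20 to 40 min and 1 fell from 40 to 60 min, and the list did not pass camera, a test that sets a list against other genes, at any of the 3 steps (1 up, 2 up, and 1 up with 1 down adjusted over the list alone). CLN1, although labelled deleted, was well above background in both channels on all 12 arrays, and its ratio went from -0.04 at 5 min to 0.94 at 60 min. The change of CLN1 from 20 to 40 min was 0.48 ± 0.11 (limma adjusted p = 0.0039), and 0.35 (limma adjusted p = 0.336) with the slide as a term. The position of the CLN1, CLN2 and CLN3 probes relative to the deleted parts is not known here, and a probe outside the deleted part checks nothing.

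**Figure D1:**
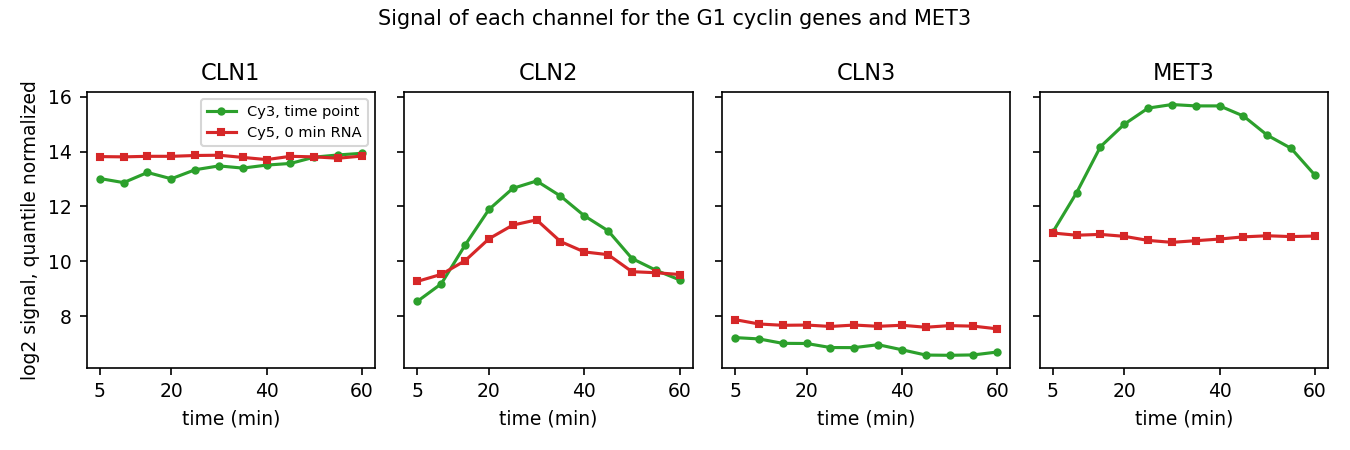
Log2 signal after quantile normalization (vertical axis) against time in min (horizontal axis) for CLN1, CLN2, CLN3 and MET3, with 1 point per array. Green circles are Cy3, the time point RNA, and red squares are Cy5, the 0 min RNA; the Cy5 line of CLN2 rises from 9.27 at 5 min to 11.5 at 30 min.

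Over the whole course the abundance of many genes followed the time. Of the 6149 genes, 4000 (65.1%) passed the moderated F test for a smooth curve from 5 to 60 min, and 1322 of these had a fitted range of at least 1 on the log2 scale. With the slide as a term 2711 genes passed, of which 2642 were among the 4000. Without the 55 min array 2976 passed and without the 60 min array 2938, so whether most genes were called depended on the setting. With the 8 arrays of the second slide alone 2602 passed. That fit covered only the later part of the course, so its count and the 4000 are not for the same curve. The median log2 ratio was highest at 30 min for the methionine list, at 40 min for the targets of the G1/S factors SBF and MBF, at 50 min for the histone genes and at 60 min for the CLB2 cluster of mitotic genes.

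**Figure D2:**
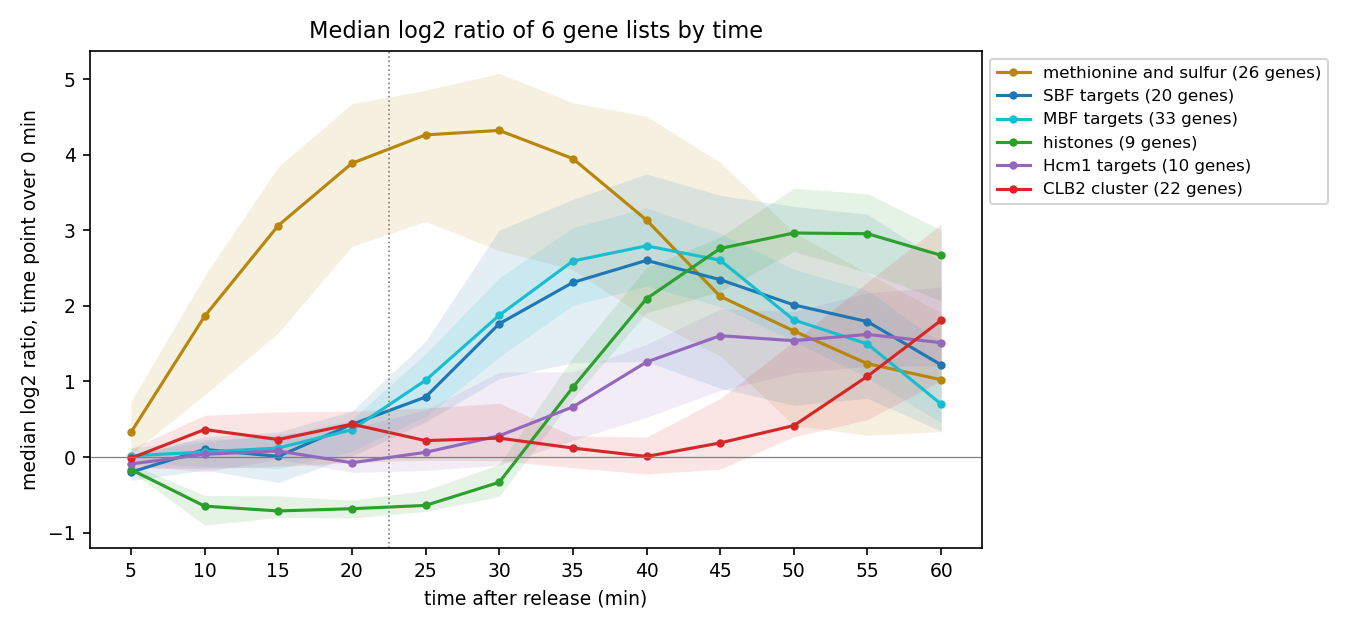
Median log2 ratio of time point over 0 min (vertical axis) against time in min (horizontal axis) for 6 gene lists, with 1 point per array. The bands span the quartiles of the genes and the dotted line marks the change of slide; the median of the 26 methionine genes reaches 4.32 at 30 min, that of the 33 MBF targets 2.79 at 40 min and that of the 9 histone genes 2.96 at 50 min.

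From 5 to 20 min the main change was a rise of the genes for sulfate assimilation and methionine synthesis. Of the 26 genes of this list 24 rose and none fell, with a median change of 3.08 (24 also when adjusted over the list alone). The median was 3.21 both with the slide as a term and within the first slide. The list shifted against other genes (camera adjusted p = 1.13e-40), also with an estimated correlation (adjusted p = 0.00091). The largest rises of all named genes were those of STR3, a cystathionine beta-lyase, at 5.15 ± 0.34 (SE), SEO1, a putative permease, at 4.72 ± 0.24, the sulfate permease gene SUL2 at 4.69 ± 0.16, the arylsulfatase gene BDS1 at 4.34 ± 0.23 and MET5, a subunit of sulfite reductase, at 4.32 ± 0.20. Their adjusted p in limma were at most 1.63e-06. The largest falls were those of HXT1, a low-affinity glucose transporter, at -2.82 ± 0.24 (limma adjusted p = 1.29e-05), FMP48 at -2.56 ± 0.24, MPC3, a subunit of the mitochondrial pyruvate carrier, at -2.52 ± 0.33, the protein kinase gene RCK1 at -2.45 ± 0.28 and CCW22 at -2.15 ± 0.56. The fall of CCW22 had an adjusted p of 0.0387 in limma, and 0.118 with the slide as a term (-1.65), and its call was also lost without the 25, 40, 45, 50, 55 or 60 min array (highest adjusted p = 0.111). It was lost too with scale normalization (-0.63, adjusted p = 0.364), a spline of 3 degrees of freedom (-1.48, 0.164), Feature Extraction's processed signals (0.0586), the authors' deposited table (0.0585) and eBayes with trend and robust (0.0658). The log2 ratio of CCW22 was -1.31 at 5 min, -2.74 at 20 min, -1.41 at 35 min, -1.71 at 40 min and -3.15 at 45 min, so its fall was not kept at 35 and 40 min. With scale normalization the rises of STR3 and SEO1 were 2.96 and 3.11. With a curve through 0 at 0 min the changes of HXT1, FMP48, MPC3 and RCK1 were -1.80, -1.33, -1.33 and -1.30.

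Of the 20 SBF targets 5 rose and none fell (6 adjusted over the list alone), with a median of 0.50, led among the named members by the cyclin gene PCL1 at 1.36 ± 0.27 and the repressor gene YOX1 at 1.06 ± 0.20. Of the 33 MBF targets 4 rose (5 adjusted over the list alone), with a median of 0.23, among them RNR1, the large subunit of ribonucleotide reductase, at 1.27 ± 0.23. Of the 9 histone genes 1 fell, HTA2 at -1.39 ± 0.34, with 7 falling when adjusted over the list alone and a median of -0.52. Of the 22 CLB2 cluster genes 4 rose (10 rose and 3 fell adjusted over the list alone), with a median of 0.38. These 4 lists passed camera with the preset correlation. With an estimated correlation the adjusted p was 0.325 for the SBF targets, 0.502 for the MBF targets, 0.343 for the histone genes and 0.314 for the CLB2 cluster. None of the 10 Hcm1 targets and none of the 9 genes of the MCM cluster, which holds the replicative helicase, passed (0 and 2 adjusted over the list alone). The MCM list did not pass camera in the main fit (median 0.41), but gained a call with the slide as a term (0.43) and within the first slide (0.37).

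The genes of protein synthesis and carbon metabolism were also examined over this interval. Of the 138 cytosolic ribosomal protein genes 15 fell and none rose (43 fell adjusted over the list alone), with a median of -0.43, as in RPS10B at -1.49 ± 0.38, whose call was lost with the slide as a term (-1.21, limma adjusted p = 0.121), with a spline of 3 degrees of freedom (-0.91, adjusted p = 0.248) and without the 25, 40, 45, 50, 55 or 60 min array (highest adjusted p = 0.107). Of the 36 ribosome biogenesis genes 5 rose (9 adjusted over the list alone), with a median of 0.23. Of the 14 glucose-repressed genes 4 fell and 1 rose (7 and 2 adjusted over the list alone), with a median of -0.36, and the falls included ADH2, the alcohol dehydrogenase of ethanol use, at -1.70 ± 0.24 and the activator gene CAT8 at -1.46 ± 0.15. The log2 ratio of RPS10B was -0.24 at 5 min, -1.50 at 20 min, -0.25 at 35 min, -0.39 at 40 min and -1.47 at 45 min. Its fall was thus not kept at 35 and 40 min and came back at 45 min. With a curve through 0 at 0 min RPS10B, ADH2 and CAT8 changed by -0.82, -0.55 and -0.85. With an estimated correlation the camera adjusted p of these 3 lists was 0.355, 0.147 and 0.314. The following lists did not pass camera: 2 of 12 phosphate genes fell, with PHM6 at -0.82 ± 0.20, and adjusted over the list alone 7 fell and 2 rose. In the pheromone response list 1 of 16 genes fell (7 adjusted over the list alone), and the list gained a camera call with the slide as a term (median -0.25) and within the first slide (-0.26). In the stress list 1 of 25 genes rose, YGP1 at 1.07 ± 0.13 (1.71 with a spline of 3 degrees of freedom), and 1 fell (1 and 2 adjusted over the list alone). In the Gcn4 list of amino acid synthesis 1 of 20 genes rose and 1 fell, LYS20 at -0.47 ± 0.12 (1 and 3 adjusted over the list alone). No gene of the alpha-specific list (4 genes) or of the meiosis list (15 genes), both fixed beforehand as presumed markers of other cell types, passed, nor when adjusted over the list alone.

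With the slide as a term, the medians of 7 lists other than methionine that passed camera were 0.53 for SBF, 0.25 for MBF, -0.43 for histones, 0.32 for the CLB2 cluster, -0.41 for ribosomal proteins, 0.23 for ribosome biogenesis and -0.35 for glucose-repressed genes. Within the first slide they were 0.49, 0.23, -0.43, 0.32, -0.41, 0.23 and -0.35. Scale normalization ended the calls of MBF (0.045), histones (-0.41) and ribosome biogenesis (0.15), and a spline of 3 degrees of freedom that of ribosome biogenesis, with a changed sign (-0.00078).

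In all 558 of 6149 genes changed from 5 to 20 min, 292 up and 266 down (limma contrast, Benjamini-Hochberg 0.05), of which 131 rose and 75 fell at least 2-fold. The share that rose, 52.3%, went below that which fell with median centring (46.3%), Cy3 alone (46%) and without 15 min (48%), 20 min (47.4%) or 30 min (49.2%). The count was 3528 with a curve through 0 at 0 min, 1269 with scale normalization, 353 with Feature Extraction's processed signals and 354 with the authors' deposited table. It fell to 217 with the slide as a term and to 261 within the first slide, a fit of a straight line to 4 arrays chosen after seeing the data, and with single arrays left out it was 1600 without 10 min, 944 without 15 min, 839 without 20 min, 270 without 25 min, 1266 without 30 min, 326 without 40 min, 303 without 50 min, 244 without 55 min and 262 without 60 min.

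From 20 to 40 min the G1/S genes rose together. All 33 MBF targets rose (33 adjusted over the list alone), with a median change of 2.21, and 18 of the 20 SBF targets rose and none fell (19 rose adjusted over the list alone), with a median of 2.13. With the slide as a term the medians were 2.63 and 2.58. The largest rises of all named genes were those of TOS4 at 5.93 ± 0.12 (SE; limma adjusted p = 2.52e-11), the cohesin subunit gene MCD1 at 5.06 ± 0.15, CSI2 at 4.67 ± 0.15, PCL1 at 4.29 ± 0.20 and RNR1 at 4.28 ± 0.16. The endonuclease gene HO rose by 4.23 ± 0.26 and YOX1 by 3.66 ± 0.14. The S-phase cyclin gene CLB6 rose by 3.79 ± 0.26. It was not well above background in Cy3 at 5, 10 and 15 min, and in Cy5 it was well above background on 4 of the 12 arrays, so its ratio compresses the change; its Cy3 signal was at least 26.5-fold higher at 40 than at 5 min. All 9 histone genes rose (9 adjusted over the list alone), with a median of 2.68, as HTA2 did by 3.82 ± 0.24 and HHF1 by 3.01 ± 0.12. All 10 Hcm1 targets rose (10 adjusted over the list alone), with a median of 0.97, led by the microtubule regulator gene STU2 at 2.08 ± 0.12 and WHI5, the repressor of SBF, at 1.34 ± 0.11. These 4 lists passed camera with the preset correlation, and with an estimated correlation their adjusted p was 0.0702 for MBF, 0.0588 for SBF, 0.0894 for histones and 0.0542 for Hcm1. The highest adjusted p of these 4 lists was 5.4e-07 in fry of limma, which tests whether the genes of a list move one way and does not set them against other genes.

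Over the same interval the methionine list moved both ways. Of the 26 genes 11 rose and 10 fell (11 and 11 adjusted over the list alone), with a median of -0.08 (0.19 with the slide as a term). The largest falls of all named genes were those of the methionine permease genes MUP3 at -3.89 ± 0.11 (limma adjusted p = 5.27e-10) and MUP1 at -3.40 ± 0.18, the glutathione and peptide transporter gene OPT1 at -2.71 ± 0.14, the transcription factor gene MET32 at -2.54 ± 0.15 and STR3 at -2.47 ± 0.25. SUL2 fell by 2.30 on the log2 scale, whereas MET3 rose by 0.82 ± 0.11 and MET5 by 0.50 ± 0.14. Of the 36 ribosome biogenesis genes 25 fell and none rose (27 adjusted over the list alone), with a median of -0.49, as NOG1 did at -1.33 ± 0.24 (call lost with a spline of 3 degrees of freedom, -0.94, limma adjusted p = 0.062), and the list passed camera with a preset and with an estimated correlation (adjusted p = 6.13e-09 and 0.032). The median log2 ratio of this list was -0.16 at 30 min, -0.31 at 35 min, -0.12 at 40 min and 0.04 at 45 min. NOG1 was at 0.74, -0.47, -0.11 and 0.92 at these times, so its fall was not kept at 45 min. Of the 16 pheromone response and a-specific genes 9 fell and 1 rose (10 and 2 adjusted over the list alone), with a median of -0.37, among them the protease gene BAR1 at -1.58 ± 0.11 and the pheromone gene MFA1 at -1.14 ± 0.13; the adjusted p with an estimated correlation was 0.147. Of the 138 ribosomal protein genes 26 rose and 4 fell, but only 2 and 1 when adjusted over the list alone, and the adjusted p with an estimated correlation was 0.667. The call of this list was lost with a spline of 3 degrees of freedom (adjusted p = 0.106) and without the 35 min array (0.0796) or the 50 min array (0.087). Its median log2 ratio was -0.60 at 30 min, -0.25 at 35 min, -0.36 at 40 min and -0.58 at 45 min.

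The following lists did not pass camera from 20 to 40 min. In the CLB2 cluster 8 of 22 genes fell and 3 rose, as many as when adjusted over the list alone. In the MCM cluster 5 of 9 fell and 2 rose, also when adjusted over the list alone, with FAR1, an inhibitor of the cyclin-dependent kinase, at -1.77 ± 0.15. The replication licensing gene CDC6 changed by 1.01 ± 0.23, a call that was lost with the slide as a term (0.91, limma adjusted p = 0.254) and with a spline of 3 degrees of freedom (0.28, adjusted p = 0.681), and it changed by 0.60 with a curve through 0 at 0 min. Of the 25 stress genes 12 rose and 5 fell (12 and 5 adjusted over the list alone), with HSP12 at 1.51 ± 0.17 and SPI1 at -1.16 ± 0.12. Of the 20 Gcn4 targets 6 fell and 1 rose (6 and 1 adjusted over the list alone), of the 14 glucose-repressed genes 3 rose and 2 fell (2 and 2), including SUC2, invertase, at -1.55 ± 0.16, and of the 12 phosphate genes 4 rose and 2 fell (4 and 2). Among the presumed markers of other cell types 2 of 4 alpha-specific genes fell, and 4 of 15 meiosis genes rose and 3 fell, the same counts as when adjusted over the list alone.

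In all 2780 genes changed from 20 to 40 min, 1506 up and 1274 down, of which 273 rose and 142 fell at least 2-fold. The share that rose was 54.2%, but 48.7% with Feature Extraction's processed signals, 48.7% with the authors' deposited table and 45.1% with Cy3 alone, so which direction held more genes depended on the setting. This interval spans the change of slide, and with the slide as a term the count was 708 (443 up and 265 down), of which 701 were among the 2780. No value within a slide can be had for it. The slide term overlaps with a change across this interval, which costs precision. Calls lost with the term thus do not show that those genes differed by slide. With the slide as a term the medians were 2.90 for the histones, 0.93 for Hcm1, -0.55 for ribosome biogenesis, -0.60 for the pheromone response genes and 0.40 for ribosomal proteins.

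From 40 to 60 min the mitotic genes rose and the G1/S genes fell. Of the 22 CLB2 cluster genes 18 rose and none fell (20 adjusted over the list alone), with a median change of 1.73 (1.72 with the slide as a term and 1.72 within the second slide). The list passed camera with a preset and with an estimated correlation (adjusted p = 3.46e-19 and 0.004). The largest rises of all named genes were those of the cytokinesis gene HOF1 at 4.58 ± 0.21 (SE; limma adjusted p = 1.9e-07), the B-type cyclin gene CLB1 at 4.19 ± 0.21, the transcription factor gene SWI5 at 3.68 ± 0.26, the B-type cyclin gene CLB2 at 3.30 ± 0.33 and IRC8 at 3.13 ± 0.14. Of the 33 MBF targets 30 fell and 1 rose (31 and 1 adjusted over the list alone), with a median of -2.06, and of the 20 SBF targets 14 fell and 1 rose (15 and 1), with a median of -0.98. The changes of TOS4, RNR1, MCD1 and HO were -2.40, -2.69, -2.66 and -2.88. Within the second slide the medians were -2.08 and -1.02, and the adjusted p with an estimated correlation was 0.075 for MBF and 0.171 for SBF. Of the 10 Hcm1 targets 6 rose (7 adjusted over the list alone), with a median of 0.68, including the forkhead factor gene FKH1 at 1.51 ± 0.10, and of the 9 histone genes 5 rose (6 adjusted over the list alone), with a median of 0.75; the adjusted p with an estimated correlation was 0.0815 and 0.325.

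The methionine genes fell over the same interval. Of the 26 genes 24 fell and none rose (25 adjusted over the list alone), with a median of -1.68 (-1.72 within the second slide), and the list passed camera with a preset and with an estimated correlation (adjusted p = 1.27e-22 and 0.0034). The largest falls of all named genes were those of SEO1 at -4.40 ± 0.22, the S-methylmethionine permease gene MMP1 at -3.70 ± 0.25, the homocysteine methyltransferase gene MHT1 at -3.65 ± 0.31, STR3 at -3.62 ± 0.32 and the cysteine transporter gene YCT1 at -3.47 ± 0.23. Of the 9 MCM cluster genes 5 fell (6 adjusted over the list alone), with a median of -0.67, as MCM5 did at -1.24 ± 0.22 and SWI4, the DNA-binding subunit of SBF, at -1.83 ± 0.34. Of the 25 stress genes 10 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.41, and of the 16 pheromone response genes 5 fell (5 adjusted over the list alone), with a median of -0.35, among them BAR1 at -1.93 ± 0.15 and MFA2 at -1.34 ± 0.22. Of the 138 ribosomal protein genes 16 rose and none fell (12 adjusted over the list alone), with a median of 0.12. With an estimated correlation the adjusted p was 0.339 for the MCM cluster, 0.325 for the stress genes, 0.325 for the pheromone response genes and 0.618 for the ribosomal protein genes, whose call was also lost without the 45 min array (adjusted p = 0.109). The remaining lists did not pass camera. Counts over all genes were the same as those adjusted over the list alone for the Gcn4 targets (4 rose, 3 fell), glucose-repressed genes (4 rose, 1 fell), alpha-specific genes (1 rose, 1 fell) and meiosis genes (5 rose, 3 fell). Of the ribosome biogenesis genes 2 rose (1 adjusted over the list alone), and of the phosphate genes 1 rose and 2 fell (1 and 4). MF(ALPHA)1, an alpha pheromone gene, was the alpha-specific gene that fell, at -1.89 ± 0.15. It was well above background in both channels on all 12 arrays, and the mating type of the cells was not tested.

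In all 1462 genes changed from 40 to 60 min, 597 up and 865 down, of which 116 rose and 218 fell at least 2-fold. With the slide as a term the count was 1480, with 1617 within the second slide and 960 with scale normalization. The slide as a term moved no list median of this interval by more than 0.021. It could hardly have done so, because all arrays from 40 to 60 min lay on the second slide. Scale normalization ended the calls of the histones (0.40) and pheromone response (-0.23). Within the second slide the medians were 0.67 for Hcm1, 0.80 for histones, -0.72 for the MCM cluster, -0.40 for stress, -0.37 for pheromone response and 0.11 for ribosomal proteins. The count was 945 without the 40 min array and 907 without the 55 min array.

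The order of the gene groups was compared by the half-rise time, at which the fitted curve of a gene first passed the midpoint between its minimum before the peak and its peak. The SBF targets had a median half-rise time of 25.6 min (18 genes) and the MBF targets of 26.2 min (33 genes), a difference of 0.597 min that did not pass the test (two-sided permutation test over genes, p = 0.105, adjusted p = 0.105). It passed without the 50, 55 or 60 min array, at 1.54, 1.37 and 1.43 min. The histone genes, with a median of 36.8 min (9 genes), came 10.9 min after all G1/S targets (51 genes, median 25.9 min), and the Hcm1 targets, with 34.8 min (10 genes), came 8.92 min after them (permutation p = 1e-05 for both, the smallest the resamples can give, adjusted p = 2.5e-05). The CLB2 cluster, with 49.8 min (19 genes), came 15.0 min after the Hcm1 targets (permutation test, p = 0.00946, adjusted p = 0.0158). Its median lay 13.0 min after that of the histones, which did not pass (permutation test, p = 0.0582, adjusted p = 0.0727), but passed with Feature Extraction's processed signals (14.3 min), a spline with 3 (16.3 min) or 5 (14.9 min) degrees of freedom, and without the 5, 15, 30, 35, 40, 45 or 50 min array (13.5 to 14.7 min). In the CLB2 cluster ASE1 at 9.88 min, SRC1 at 13.3 min and DBF2 at 24.2 min lay before the rest of the list, whose earliest was CLB2 at 45 min. These 3, and MNN1 at 13.0 min among the SBF targets, were singled out after their values were seen. On simulated curves, whose peaks lay at 50 min or earlier, the median difference of the fitted from the true half-rise time lay between -2.03 and -1.7 min. The median peak of the called Hcm1 targets and CLB2 cluster genes was at 60 min, the last array. For genes still rising there the half-rise time is a lower bound, which the simulated curves do not cover. The gaps that involve these lists thus depend on where sampling stopped. Genes are not independent replicates, and times closer than the 5 min between arrays rest on the fitted curve.

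**Figure D3:**
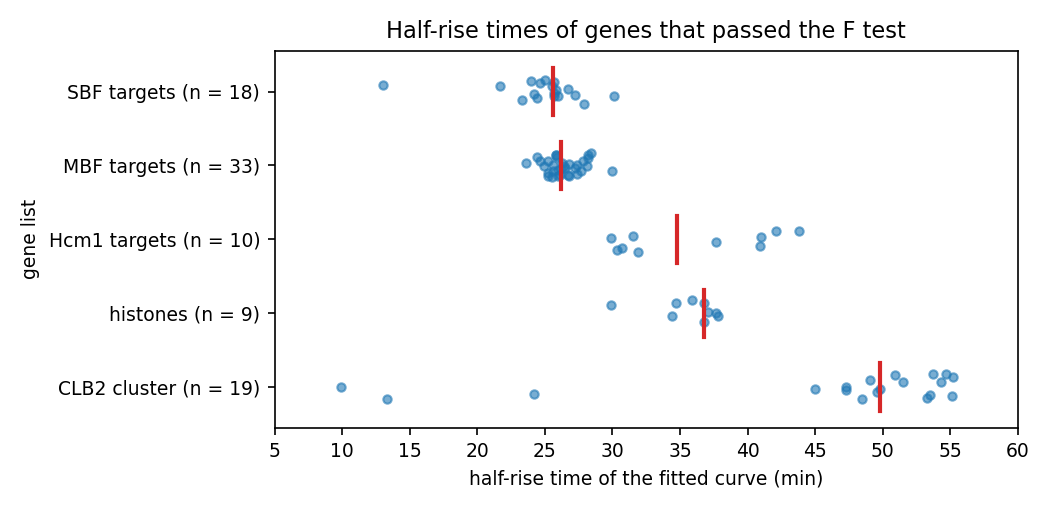
Half-rise time in min (horizontal axis) of each gene that passed the F test, by gene list (vertical axis). Each point is 1 gene, spread vertically at random, and the red bar is the median of the list, from 25.6 min for the SBF targets to 49.8 min for the CLB2 cluster.

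The Cy5 channel, which held the same 0 min RNA on every array, served as a control for calls that come from hybridization and scanning. Differences in harvest, RNA isolation or labelling of the single Cy3 sample of each time point cannot appear in it. The same F test on log2 Cy5 called 152 of 6149 genes, against 4000 for the ratio, and 7 of the 152 had a fitted range of at least 1. Cy5 was quantile normalized and the ratio loess normalized, so these counts do not give the share of ratio calls that come from the cells. The median SD of a gene over the 12 arrays was 0.0415 in Cy5 and 0.247 in Cy3. The count of this reference channel control was 85 with the slide as a term, 66, 97, 81, 72 and 63 without the 5, 15, 30, 55 and 60 min arrays, and 422 when Cy5 was taken after loess and quantile normalization of the average intensities, a setting in which Cy3 enters the Cy5 value.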

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

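The tests of reversed dyes, withdrawn methionine, spill, slides, noise and array order, and the required size of the link between CLN2 and MET3, were chosen after the results were seen, while the bounds for the opposite-strand test were written before its result. The 0 min RNA lay in Cy5 on all 12 arrays, so its signal should be constant, and 7 genes were singled out because their Cy5 signal passed the F test with a fitted range of at least 1. The Cy5 range was 2.17 for CLN2, 1.51 for MET2, 1.22 for YHP1, 1.20 for GCN4, 1.18 for YNL276C, 1.12 for TOS6 and 1.02 for YIR016W, and the correlation of Cy5 with Cy3 over the arrays was 0.968, 0.974, 0.91, 0.421, 0.513, 0.991 and 0.826.

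Spill of the sample channel into Cy5 may be asked of these 7 genes. The 16 genes at least as bright and as risen in Cy3 as CLN2 had a median Cy5 range of 0.193, with YHP1 highest at 1.22, which argues against spill as a general cause. All 7 genes kept their calls with the slide as a term, which argues against the slides. Labelled RNA of the opposite strand stays open: over 54 of 461 pairs of an unannotated frame and its opposite-strand neighbour the rank correlation was -0.180 (Pearson -0.275, permutation p = 0.19), between the bounds set for and against it. That test predicted a fall of Cy5 at unannotated frames as the neighbour rose. The Cy5 signal of the 7 genes instead went with their own Cy3 (correlation 0.421 to 0.991). The test thus cannot decide for the annotated genes among them, such as CLN2 and MET2. No biological explanation was tested.

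The labels say that methionine was added at release, yet the methionine genes rose, and the MET3 promoter is repressed by methionine as background. Reversed dyes would make Cy3 the constant channel, but the median SD of a gene over the arrays was 5.97 times larger in Cy3 than in Cy5. Withdrawal of methionine at release is a candidate explanation: CLN2 rose by 1.88 from 5 to 20 min and followed MET3 over the 12 arrays (Pearson r = 0.963, Spearman rho = 0.965, permutation p = 1e-05 for both, the smallest the resamples can give). The r was 0.955 without 5 and 10 min, 0.989 within the first slide of 4 arrays and 0.974 within the second of 8, and the time points are serially dependent. The size of the CLN2 ratio is uncertain, because its Cy5 signal, which should be constant, moved over a fitted range of 2.17. With methionine repressing the MET3 promoter, the labelled order would turn down the only labelled source of a G1 cyclin at release. Of the 26 methionine genes 24 rose and none fell from 5 to 20 min, and MET3 rose by 4.16. For these genes the values argue against methionine having been added at release. What was done to the culture is not recorded beyond the labels, so withdrawal itself was not observed. From 40 to 60 min 24 of the 26 methionine genes fell and none rose, and the list median at 60 min was 1.02. Withdrawal at release does not by itself account for this later fall, whose cause was not tested.

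Between 30 and 35 min the ratios differed by a median of 0.268, the second largest of the 11 neighbouring pairs after 5 to 10 min at 0.271. The count of genes over 2-fold, 159, was the largest, against 137 from 5 to 10 min. From 40 to 45 min the median difference was 0.22, with 88 genes over 2-fold. The ribosomal protein median moved from -0.60 to -0.25 at the 30 to 35 min step and from -0.36 to -0.58 at the 40 to 45 min step. The 30 and 35 min arrays both lay on the second slide. Hybridization and scanning noise stays open: the median difference from 30 to 35 min was 6.71 times larger in Cy3 than in Cy5, but this sets single samples against 1 repeated RNA, and the ratio was at least 2.62 for every neighbouring pair. A difference in the culture or in sampling could not be tested with 1 sample per time.

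The order of the 12 arrays was permuted to give 100 orders, the real one included. As many genes over 5 to 60 min came from 1 order, the real one (4000, highest other 1187), and likewise 1 order from 20 to 40 min (2780, highest other 1634) and 1 from 40 to 60 min (1462, highest other 747). From 5 to 20 min 2 orders gave as many (558, highest other 1308). At most 2 of the 100 orders gave as many for each of the 4 counts. The order that gave 1187, 1308 and 1634 calls, with a rank correlation of -0.133 with the real one, gave more than 2 times the real 5 to 20 min count, and why was not tested. Shuffling breaks any gradual trend, so these counts cannot tell a trend in the cells from a drift of the arrays. No order was fitted with the slide as a term, with which the real counts were 217 from 5 to 20 min and 708 from 20 to 40 min.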

How the results depend on the processing

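Scale normalization, Cy3 alone, the first slide alone, and for the lists the second slide alone, no background subtraction, median centring and scale normalization, were chosen after seeing the data. Median signals of at least 1688 stood against background medians of at most 50, and the number of arrays limits the precision. For the named genes, 4264 values kept their side of the threshold and, for changes, their direction, 142 lost a call, 14 gained 1 and 2 changed sign, both without a call: with median centring the change from 20 to 40 min was 0.11 for CLN3 and 0.11 for MF(ALPHA)2. This tally overstates stability. Its 167 Aquantile values could not change, and the 167 of the authors' table nearly repeat Feature Extraction's. Most of these genes were also picked for large changes in the main fit. Among list shifts 938 values stayed on their side, 30 lost a call, 19 gained 1 and 33 changed sign. Unless stated, the cause of a change was not tested. The brightest probe was not run because each gene has 1 probe, and Aquantile leaves ratios as they were, so it tests nothing for the ratio counts.

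The count from 5 to 20 min, 558, became 353 with Feature Extraction's processed signals, 354 with the authors' deposited table, 217 with the slide as a term, 261 within the first slide, 3528 with a curve through 0 at 0 min and 1269 with scale normalization. All 217 genes called with the slide as a term were among the 558, as were 228 of the 261. From 20 to 40 min, 2780 became 708 with the slide as a term, and from 40 to 60 min 1462 became 960 with scale normalization. The count over 5 to 60 min, 4000, became 2602 within the second slide, which has fewer arrays and holds only the later times. The reference channel control, 152, became 422 with Aquantile and 85 with the slide as a term. With each time point left out the counts ran from 2938 to 4568 over 5 to 60 min, 244 to 1600 from 5 to 20 min, 2108 to 3242 from 20 to 40 min, 907 to 1880 from 40 to 60 min and 63 to 165 for the reference channel control, which was 66 without 5 min, 97 without 15 min, 81 without 30 min, 72 without 55 min and 63 without 60 min. CLN3 at 30 min moved to -0.69 with Feature Extraction's signals.

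Half-rise of the CLB2 cluster minus histones passed at 14.3 min with Feature Extraction's signals, 16.3 min with 3 and 14.9 min with 5 degrees of freedom, and ran from 11 to 14.7 min with a time point left out. MBF minus SBF ran from 0.133 to 1.54 min. The other 3 pairs kept their calls in every setting run.

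With a correlation estimated by camera, these medians, unchanged by that setting, lost their calls. From 5 to 20 min they were 0.38 for CLB2, 0.23 for MBF, 0.50 for SBF, -0.43 for ribosomal proteins, -0.36 for glucose-repressed genes, -0.52 for histones and 0.23 for ribosome biogenesis. From 20 to 40 min they were 0.97 for Hcm1, 2.21 for MBF, 2.13 for SBF, 0.20 for ribosomal proteins, 2.69 for histones and -0.37 for pheromone response. From 40 to 60 min they were 0.68 for Hcm1, -2.06 for MBF, -0.67 for MCM, -0.98 for SBF, 0.12 for ribosomal proteins, -0.41 for stress, 0.75 for histones and -0.35 for pheromone response.

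With scale normalization the calls of MBF (0.045), histones (-0.41) and ribosome biogenesis (0.15) from 5 to 20 min were lost, as were those of histones (0.40) and pheromone response (-0.23) from 40 to 60 min. MCM from 5 to 20 min (0.68) and glucose-repressed genes from 40 to 60 min (0.21) gained calls, and Gcn4 from 5 to 20 min (0.022), the engineered cyclins (0.046) and ribosome biogenesis (0.0077) from 40 to 60 min changed sign without a call. With 3 degrees of freedom ribosomal proteins from 20 to 40 min lost the call (0.12) and ribosome biogenesis from 5 to 20 min lost it with a changed sign (-0.00078). Calls were gained by MCM (0.76), the engineered cyclins (0.25) and stress (0.20) from 5 to 20 min and by Gcn4 (-0.20) and MCM (-0.59) from 20 to 40 min, and Gcn4 (0.077) and Hcm1 (-0.17) from 5 to 20 min and ribosome biogenesis from 40 to 60 min (0.11) changed sign. With 5 degrees of freedom MCM from 5 to 20 min (0.48) and glucose-repressed genes from 40 to 60 min (0.21) gained calls, and methionine from 20 to 40 min (0.028) and ribosome biogenesis from 40 to 60 min (0.012) changed sign. With the slide as a term MCM (0.43) and pheromone response (-0.25) from 5 to 20 min gained calls, and methionine from 20 to 40 min (0.19) changed sign. Within the first slide MCM (0.37) and pheromone response (-0.26) from 5 to 20 min gained calls, and within the second ribosome biogenesis from 40 to 60 min (0.013) changed sign. Median centring turned Gcn4 (0.041) and meiosis (0.070) from 20 to 40 min and gave MCM from 5 to 20 min a call (0.43). From 40 to 60 min no background subtraction turned the engineered cyclins (0.022), and Feature Extraction's signals turned the engineered cyclins (0.057), ribosome biogenesis (0.021) and the alpha-specific genes (-0.013).

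With a time point left out, the medians from 5 to 20 min ran from -0.083 to 0.013 for Gcn4, which changed sign without 15 min, and from 0.40 to 0.51 for MCM, which gained a call without 10, 15 or 25 min. From 20 to 40 min they ran from -0.12 to 0.0033 for Gcn4, 0.12 to 0.27 for ribosomal proteins and -0.14 to 0.058 for methionine. From 40 to 60 min they ran from -0.025 to 0.025 for the alpha-specific genes, -0.033 to 0.051 for the engineered cyclins, -0.032 to 0.013 for ribosome biogenesis, 0.026 to 0.18 for ribosomal proteins and 0.11 to 0.27 for glucose-repressed genes, which gained a call without 50 or 55 min.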

Other observations

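The lists and genes here were chosen after the named genes were seen. The purine biosynthesis list fell in both later intervals: 8 of 11 genes fell from 20 to 40 min (8 fell and 1 rose adjusted over the list alone), with a median of -0.56, and 6 of 11 fell from 40 to 60 min (7 adjusted over the list alone), with a median of -0.51. Its camera p, adjusted over all 20 lists and 3 contrasts, was 0.00157 and 0.000955, and with an estimated correlation 0.0607 and 0.0571, so both calls were lost. From 20 to 40 min ADE17, a bifunctional enzyme of the last steps of the pathway, changed by -1.52 ± 0.14 and ADE2 by -1.11 ± 0.10. From 5 to 20 min 2 fell and 1 rose (3 and 1 adjusted over the list alone), with a median of 0.011, and the list did not pass. The median was 0.011 and the mean -0.047.

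Of the 7 hexose transporter genes 5 fell from 5 to 20 min (6 adjusted over the list alone), with a median of -1.16, and the camera adjusted p was 6.13e-06, or 0.0977 with an estimated correlation, which ended the call. HXT1 changed by -2.82 ± 0.24, HXT2, a high-affinity transporter, by -2.02 ± 0.30 and HXT3 by -1.03 ± 0.12. HXT6 and HXT7 are near-identical copies, so their values are uncertain, and HXT7 at -1.16 ± 0.33 had a limma adjusted p of 0.0503. From 20 to 40 min 1 rose (1 adjusted over the list alone), HXT5 at 0.64 ± 0.09, with a median of 0.24. From 40 to 60 min 3 rose (3 adjusted over the list alone), including HXT1 at 1.46 ± 0.22, while the median was -0.38 and the mean 0.054, which differ in sign. Neither later interval passed camera.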
